A study of Mus musculus with 4 samples.

How the data were processed

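DNA methylation was measured by enzymatic methyl-seq (EM-seq) in 4 libraries of lineage-negative (Lin–) bone marrow cells from 2-month-old mice. The labels are not uniform on this: the source and tissue fields give Lin– bone marrow, which is used here, while the extraction text speaks of NE cells, and nothing in the labels settles which is right. In EM-seq, enzymes protect 5-methylcytosine and 5-hydroxymethylcytosine and deaminate unmodified cytosine, so that both modified forms are read together as methylated. The control group (Tet3F/F, 2 libraries) carried the floxed Tet3 allele without Cre, and the Tet3_cKO group (Tie2+/cre with Tet3F/F, 2 libraries) carried Cre under Tie2 control. Per the labels, 2 mice were used per genotype and 200 ng of DNA entered each library; whether each library came from a single mouse is not stated, so p-values measure the spread between these libraries.

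The deposited files hold the cytosines of each library with both strands listed apart. Column 5 is the methylation level as a fraction, as deposited by the authors, and column 6 is the count of calls at that cytosine, as deposited by the authors with no normalisation between libraries. The product of level and calls was whole within 0.005 at every site, which gave back the methylated and unmethylated counts. Cytosines with 0 calls were listed with level 0 and were treated as not measured. The submitters' processing notes name Trim Galore 0.6.7, Bismark 0.23.1, SAMtools, ChIPseeker and the mm10 build, without their roles, and the program that wrote the tables is not given in the sources used here. Some CpGs carry a mark (CpGx) in the context column; its meaning is not given in the sources used here, and it resembles a mark for possible sequence variants at the site. These are called marked CpGs. Spike-in lambda and pUC19 sequences were not analysed here.

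The calls of both strands were summed per CpG. Sequencing gave 134555856, 141900504, 138162095 and 136712429 calls in control replicates 1 and 2 and Tet3_cKO replicates 1 and 2, with median calls per CpG of 6, 7, 6 and 6. Class levels were methylated calls over all calls across autosomal CpGs with at least 5 calls in every library, which kept 8187115 of 20383623 CpGs (40.2%). Over these CpGs the 95% binomial interval of a library's level reached 0.0108 to 0.0110 percentage points to each side. Intervals and floors of 3 counts cover counting error only, since reads are not independent molecules.

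Regions were tiles of 1 kb (at least 3 CpGs and 20 calls in every library), gene ends (1 kb to each side, the same minimum), gene bodies (at least 10 CpGs and 100 calls) and low-methylated regions (20 calls). Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10. The table gives no strand and no exons, so the transcription start could not be told from the other end of a gene, and the end with the lower methylation over the 4 pooled libraries stood for the promoter. At 7143 of 19985 tested genes (35.7%) both ends lay within 20 percentage points, so that this choice is uncertain there. The gene body was the rest of the gene. Classes that need exons, untranslated regions or repeats were not computed. Low-methylated regions were found once on the pooled libraries, as runs of at least 4 CpGs whose level over 3 neighbouring CpGs lay under 50%. Those with fewer than 30 CpGs are called low-methylated regions (LMRs), those with 30 or more unmethylated regions (UMRs), and UMRs of at least 3.5 kb canyons.

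Each region was tested with limma 3.58.1 (R 4.3.3) on log2((methylated + 0.5)/(unmethylated + 0.5)), weighted by the binomial precision of each library, with moderated variances and Benjamini-Hochberg adjustment over all regions of a kind. A region was called at an adjusted p under 0.05, 2-sided. Values written as log2 odds ratio ± SE come from this fit with 2 libraries per group. Class levels were compared by an exact permutation test, 2-sided; with 2 libraries against 2 there are 3 splits, and the smallest p is 0.333. By chance both Tet3_cKO libraries lie above both controls in 16.7% of regions, and below both in 16.7%. The other splits of the 4 libraries were fitted in the same way for comparison. Each puts 1 library of each genotype in both groups, so a genotype difference enters their residual variance and can lower their counts. Sex chromosomes were left out of the tests, since the labels give no sex.

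Before the data were examined, 15 gene lists were fixed: stem cell regulators, erythroid, megakaryocyte, myeloid, lymphoid, mast cell with basophil and eosinophil, endothelial, stromal, mature T and natural killer cell, methylation machinery, imprinted, germline, developmental, inflammation and housekeeping genes. The endothelial, stromal and mature T and natural killer lists are markers of other cells that a Lin– preparation could hold. They were tested at gene ends with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation. The groups, tests, alternatives and the rule for named genes were fixed at the same time. That rule took the called gene ends and gene bodies with the largest changes, or up to 5 of lowest unadjusted p in each direction where fewer were called, then the 5 called tiles and low-methylated regions with the largest change in each direction. It also took every called list member, the 2 members of lowest p in each list, and Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Tek, Gata2, Runx1, Spi1, Gata1, Klf1, Kit and Meis1.

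Autosomal windows of 1 Mb with at least 4 marked CpGs per 1000 in any library were called variant-rich (643 of 2470 windows, 26.0%), and the others variant-poor; these names rest on reading the mark as a possible variant. Windows in which both libraries of a group exceeded both of the other group by at least 1.5 times in marked CpGs, with at least 4 per 1000, were called group-separating. Coverage of Tek and Tet3 was compared in 1-kb windows as calls per CpG relative to the autosomal mean of the library.

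The alternatives varied the call minimum, the tile size, the gene end window, the level that defines a low-methylated region, the weights, the threshold, the sites of high coverage, the depth, the sex chromosomes and the replicate block. Each library was also left out in turn, and edgeR 4.0.16 with its quasi-likelihood test was run on methylated and unmethylated counts. Removal of marked CpGs, restriction to variant-poor windows, removal of high-coverage CpGs from the sequence classes, LMRs within 20 kb of list genes and camera on gene bodies were added after the data were seen. The tests were tested on simulated data with 200 changed regions of each kind. Differences of 10, 20 and 30 percentage points were recovered in 1.49%, 7.46% and 37.9% of changed tiles (of 1727946 tiles), 29.9%, 79.1% and 87.9% of changed gene ends (of 19985), 85.1%, 100% and 100% of changed gene bodies (of 17642), and 10.4%, 19.4% and 27.3% of changed low-methylated regions (of 83715). Unchanged regions gave 7 false calls of tiles, beside 1, 5 and 25 recovered, and 6 of low-methylated regions, beside 7, 13 and 18. They gave 2 of gene ends and 22 of gene bodies, the latter beside 57, 67 and 66. The simulated variances were more uniform than the real ones, so real recovery may be lower. Prior degrees of freedom were 36.0 simulated and 17.8 real for tiles, and the real value was lower for the other kinds too. Camera recovered a simulated shift of 10 points in the stem cell list and called 0 of the others. The result of 1 called gene body is not reported here. Data handling used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, the R packages arrow 21.0.0 and data.table (1.17.8).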

Results

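TET3 is 1 of 3 TET dioxygenases that oxidise 5-methylcytosine, a step toward the removal of methylation. The comparison asked how CpG methylation differs in Lin– bone marrow cells, a mixture of blood stem cells and early progenitors, when Tet3 is deleted through Tie2-driven Cre. Cre from a Tie2 transgene acts in endothelial cells and in the blood cells that descend from them. EM-seq libraries were made from 2 control and 2 Tet3_cKO preparations. The total was 134555856 and 141900504 CpG calls in the control libraries and 138162095 and 136712429 in the Tet3_cKO libraries, or 6.42, 6.77, 6.59 and 6.40 calls per autosomal CpG. Cytosines without a call made up 13.1%, 12.2%, 12.6% and 12.7% of those listed. Coverage of the X chromosome relative to autosomes was 0.433, 0.439 and 0.435 in control replicates 1 and 2 and Tet3_cKO replicate 1 and 0.868 in Tet3_cKO replicate 2. The corresponding values for the Y chromosome were 0.0925, 0.0983, 0.0944 and 0.0085, so that the last library stood apart from the others.

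Coverage at the genes of the design differed between the genotypes in a few short intervals. At Tet3 (chromosome 6, 83362373 to 83457208, mm10), 7 neighbouring CpGs between 83385908 and 83386004 had 0 calls in both Tet3_cKO libraries and 43 and 44 calls in the control libraries. A count of 0 allows up to 3 calls, or at most 0.065 and 0.067 of the mean coverage in the 2 libraries. The gap between the nearest covered CpGs, at 83385690 and 83386509, was 819 bp. Runs of this kind, of at least 5 CpGs, were found at 17 places in the genome, 8 of them in variant-poor windows; the 1 in Tet3 lay in a variant-rich window. Over the 106 windows of 1 kb across Tet3 the median ratio of Tet3_cKO to control coverage was 1.01. The annotation used here has no exons, so the position of these CpGs relative to the exons of Tet3 was not analysed. At Tek, which encodes Tie2 (chromosome 4, 94739086 to 94874976), the window from 94738001 to 94739000 just outside the gene had 94 and 99 calls in control and 2128 and 2016 calls in Tet3_cKO, a ratio of relative coverage of 21.8. Of variant-poor autosomal windows with at least 3 CpGs and 100 calls in both Tet3_cKO libraries, 5 had at least 5 times the relative coverage there, 3 of them on Tek and 2 starting within 2085 bp before it. A further window at Tek, from 94840001, had a ratio of 7.02 on 1 and 0 calls in control and 0 and 7 in Tet3_cKO, and the 127 windows of Tek and its flanks with a ratio under 5 had a median of 0.966.

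**Figure D1:**
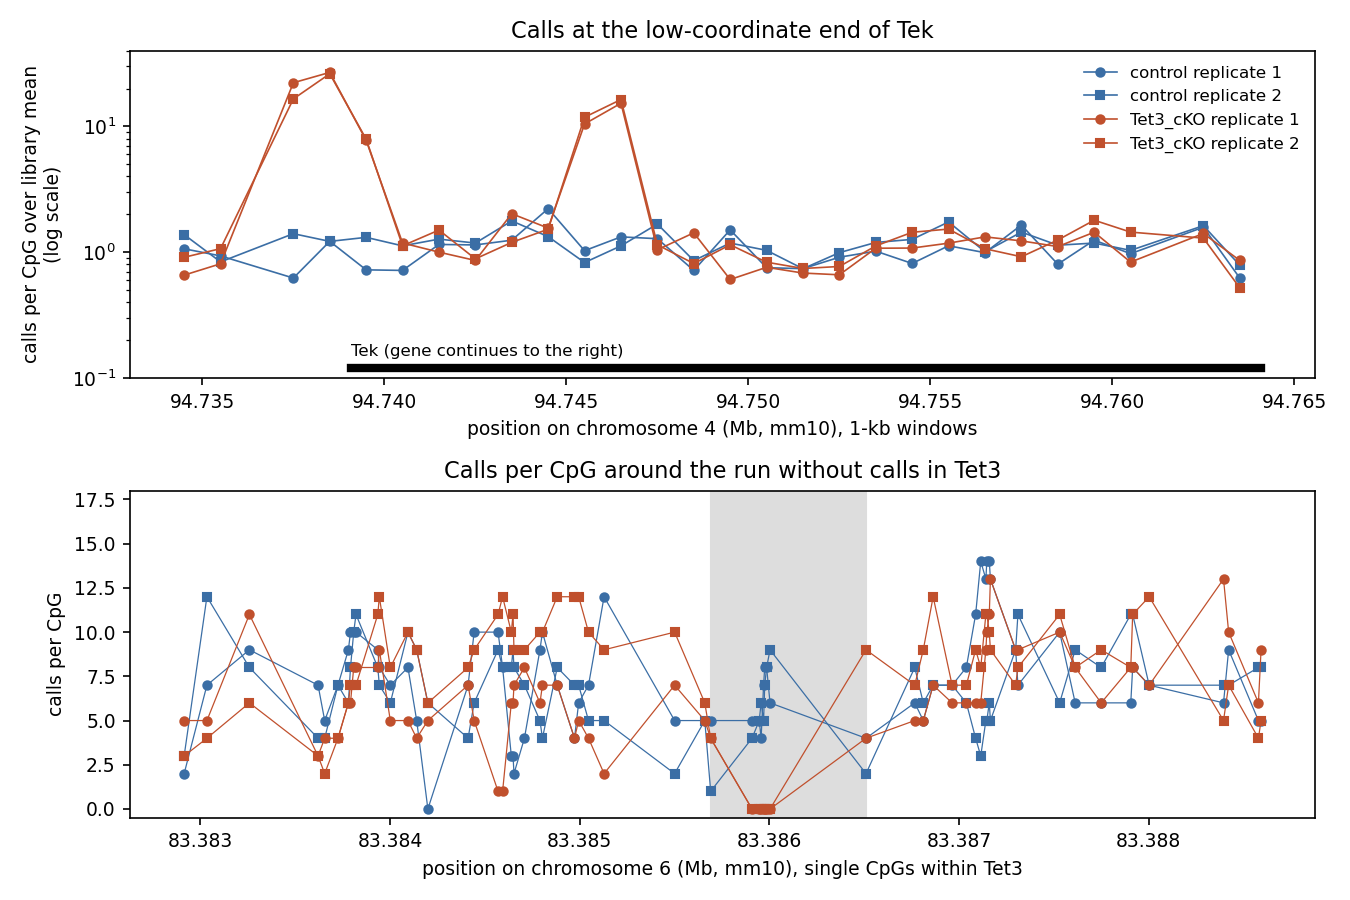
The upper panel plots calls per CpG over the library mean (log scale) in 1-kb windows at the low-coordinate end of Tek, and the lower panel calls at single CpGs in Tet3, with a colour per group, a symbol per replicate and grey for the 819 bp gap. Both Tet3_cKO libraries rise above the controls in 5 Tek windows, with a ratio of up to 21.8, and have 0 calls at the 7 CpGs in the gap.

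Methylation was slightly higher across the genome of Tet3_cKO cells, and the difference was concentrated in sequence of low methylation. The autosomal level was 68.5% ± 0.0468 in control and 69.3% ± 0.203 in Tet3_cKO (SD, n = 2 each), a difference of 0.784 percentage points. The other splits of the 4 libraries gave differences of 0.110 and 0.176 points. All 19 autosomes had both Tet3_cKO libraries above both controls, from 0.498 points on chromosome 9 to 1.22 points on chromosome 13. By feature, low-methylated gene ends stood at 26.3% ± 0.0475 in control and 27.7% ± 0.119 in Tet3_cKO (1.38 points), the rest of protein-coding genes differed by 0.854 points and sequence between genes by 0.617 points. Tiles with a mean level of 10 to 30% differed by 5.54 points and those of 30 to 50% by 5.53 points, against 0.119 points for tiles of 70 to 90%. LMRs had a level of 22.7% ± 0.763 in control and 30.8% ± 0.392 in Tet3_cKO (SD, n = 2 each), a difference of 8.11 points, with other splits at 0.817 and 0.262 points. UMRs rested at 8.26% ± 0.231 and 10.4% ± 0.0653, and sequence outside low-methylated regions at 72.4% ± 0.0861 and 72.9% ± 0.173 (SD, n = 2 each). Canyons, the long unmethylated domains, had 13.7% ± 3.02 in control and 19.5% ± 0.207 in Tet3_cKO, but 8.42% ± 0.219 and 9.76% ± 0.0380 without CpGs above 3 times the median calls. The densest CpG class, over 40 per kb, likewise differed by 2.33 points with these CpGs and by 0.725 points without them.

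For the autosomal level and for LMRs, UMRs and gene ends the exact permutation p was 0.333, the smallest that 2 libraries against 2 allow, so no class could pass a threshold of 0.05. A minimum of 10 calls per CpG, which left 113038 CpGs, moved the autosomal difference to 0.475 points, that of LMRs to 4.70 points, that between genes to 0.285 and that of the rest of protein-coding genes to 0.461, and it turned the difference outside low-methylated regions to −0.158 points. In that setting the other splits gave 0.452 and 0.0231 points for all autosomal CpGs, 0.510 and 0.120 between genes and 1.39 and 0.862 for LMRs, so that of these 3 only the LMR difference stood well above both. Other classes rose in that setting, to 7.30 points for UMRs, 7.51 for the densest CpG class, 9.96 for tiles of 10 to 30% and 10.6 for canyons. Their largest other splits were 3.17, 3.47, 4.33 and 4.70 points in that order. The canyon value rests on 827 CpGs with 261639 to 345187 calls per library. At the minimum of 5 calls, without CpGs above 3 times the median calls, the 4 differences were 1.81, 0.725, 4.09 and 1.34 points. Without Tet3_cKO replicate 2, the library with the different X and Y coverage, the LMR difference was 7.83 points.

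**Figure D2:**
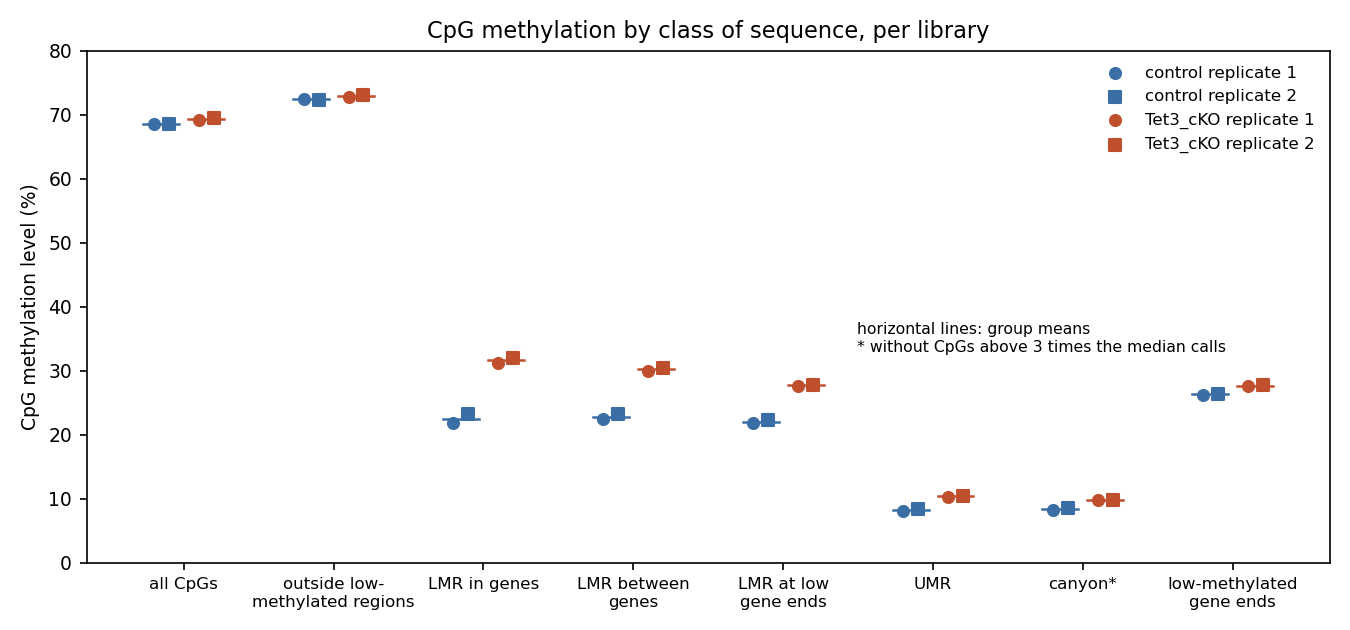
CpG methylation level in percent for each library, by class of sequence, with circles for replicate 1, squares for replicate 2 and horizontal lines for group means. In LMRs within genes, between genes and at gene ends both Tet3_cKO libraries lie above both controls by 5.69 to 9.09 points on average, against 0.498 points outside low-methylated regions.

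LMRs are short CpG-poor stretches, of 481 bp and 7 CpGs in the median here, that often coincide with distal regulatory elements. Of 83715 low-methylated regions tested with limma, 13 rose in Tet3_cKO (8 LMRs and 5 UMRs) and 0 fell. The largest rise lay in Jak2, the kinase of many cytokine receptors (chromosome 19, 29271143 to 29271556), from 9.01% and 7.38% in the control libraries to 62.4% and 59.3% in Tet3_cKO (log2 odds ratio 4.06 ± 0.32 SE, adjusted p = 0.0239). An LMR in Sgpp1, a sphingosine-1-phosphate phosphatase (chromosome 12, 75727337 to 75728020), went from 6.54% to 58.6% (4.21 ± 0.38, adjusted p = 0.0355). An LMR in Cobll1 (chromosome 2, 65170401 to 65171429) went from 13.8% to 61.9% (3.29 ± 0.27, adjusted p = 0.0239). The other LMRs with the largest rises lay 17604 bp from Ggnbp1 (chromosome 17, 26999970 to 27000431, 47.5 points) and in the non-coding gene Gm6226 (chromosome 7, 58837068 to 58837563, 44.2 points). These 5 regions were covered by 73 to 243 calls per library, and those of Jak2, Ggnbp1 and Gm6226 lay in variant-rich windows. Called regions chosen after their values were seen lay in Cytip, a cytohesin-binding protein of immune cells (a UMR, 32.6 points), in Lag3, an inhibitory receptor of lymphocytes (a UMR, 29.0 points), and in Usp6nl (an LMR, 43.3 points).

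The shift was wider than these calls. Over 67599 LMRs the median difference was 7.29 points and 79.2% were higher in Tet3_cKO, against medians of 0.712 and 0.194 points in the other splits. Both Tet3_cKO libraries lay above both controls in 46.9% of LMRs and below both in 5.21%, where chance gives 16.7% each. At an unadjusted p under 0.05, limma gave 14204 regions higher and 636 lower, against 1636 and 1542 in all for the other splits. The latter were 1.95% and 1.84% of tested regions, a low yardstick, since these splits hold the genotype difference in their residual variance. The quasi-likelihood test of edgeR called 721 regions higher and 7 lower, among them 12 of the 13. LMRs in protein-coding genes differed by 9.09 points, those outside by 7.39 points and those at low-methylated gene ends by 5.69 points. Without control replicate 1 or 2 the limma counts were 34 and 0 or 190 and 6 (higher and lower), and without either Tet3_cKO replicate 1 or 2 they were 0 and 0. They were 5 and 0 with a minimum of 50 calls, 4 and 0 without weights, 0 and 0 for regions defined at a level of 30% and 160 and 4 in variant-poor windows alone.

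**Figure D3:**
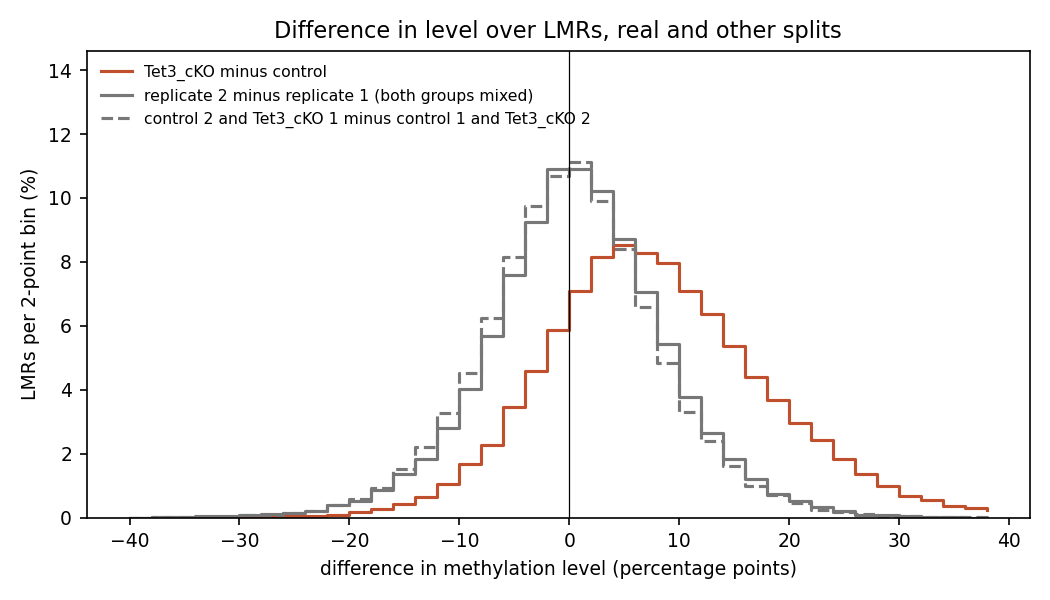
Share of LMRs in percent, in bins of 2 percentage points, by difference in methylation level, in red for Tet3_cKO minus control and in grey (solid and dashed) for the other splits of the 4 libraries. The red curve lies to the right, with a median of 7.29 points, and the grey curves have medians of 0.712 and 0.194 points.

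Fixed tiles of 1 kb located the change without prior selection of regions. Cytip held the rise with the lowest adjusted p among those named: 4 adjoining tiles (chromosome 2, 58157001 to 58161000) rose, the strongest from 12.4% to 67.2% (log2 odds ratio 3.72 ± 0.43 SE, adjusted p = 0.000576). Its adjusted p was 0.0517 without control replicate 2 and 0.0531 without Tet3_cKO replicate 1. Etv6, a repressor needed for adult blood stem cells, held 4 called tiles of 231 tested, and Tiam1, an activator of Rac, held 4 of 351. Pde4d, a cAMP phosphodiesterase, held 5 of 1047. Pde4d lay in a segment of chromosome 13, from 52 to 111 Mb, with more marked CpGs in the control libraries. Of 1727946 tiles, 1537 rose and 244 fell, and 1118 and 40 of these changed by at least 10 points. Among tiles that rose, 93.5% overlapped a low-methylated region, against 9.57% of tested tiles. Tiles that fell overlapped one as often (94.3%), so this share does not set rises apart from falls. An LMR was overlapped by 51.5% of tiles that rose and 2.46% of those that fell (6.83% of tested). Tiles that fell lay mostly in UMRs or canyons (92.6%, against 2.88% of tested) and at low-methylated gene ends (71.7%, against 2.92%).

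Of the other tiles with the largest rises, 4 lay on chromosome 18 in a segment with more marked CpGs in the control libraries. They started at 11397001 (66.5 points, 235276 bp from Rbbp8), 13052001 (55.9 points, 28300 bp from Hrh4), 15426001 (53.6 points, 15019 bp from Aqp4) and 11689001 (53.5 points, in Rbbp8). The largest decreases were in variant-rich windows too, those on chromosome 10 in a window with more marked CpGs in both Tet3_cKO libraries. They lay in Gm4924 on chromosome 10 (82373001, −49.2 points), 34383 bp from Gm1553 (82527001, −47.4 points), on chromosome 17 far from genes (54501001, −38.8 points, with 53.3% and 9.52% in the Tet3_cKO libraries and −16.9 points without Tet3_cKO replicate 2), on chromosome 13 (4943001, −38.6 points) and near Lpar1, a lysophosphatidic acid receptor, on chromosome 4 (58579001, −38.0 points). These 9 tiles had 20 to 113 calls per library. Of the calls of these and the strongest Cytip tile, all 10 ended without control replicate 2, 9 without Tet3_cKO replicate 2, 8 without Tet3_cKO replicate 1 and 7 without control replicate 1. In variant-poor windows alone 1183 tiles rose and 194 fell, where the other splits called 106 and 162 tiles; over all windows they called 134 and 200. Without control replicate 1 or 2, 465 and 117 or 625 and 128 tiles were called higher and lower, without Tet3_cKO replicate 1 or 2, 197 and 107 or 173 and 93, and without weights 48 and 11.

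Gene bodies of several regulators of blood stem cells gained methylation. Of the 27 stem cell regulators tested, 6 rose, among them Hlf (55.4% to 62.4%, log2 odds ratio 0.41 ± 0.06 SE), Etv6 (61.3% to 66.6%, 0.33 ± 0.03), Meis1 (53.9% to 58.6%, 0.27 ± 0.04), Erg (63.2% to 66.2%, 0.19 ± 0.03) and Runx1 (64.8% to 67.5%, 0.18 ± 0.03), all transcription factors, with n = 2 libraries per group. The limma adjusted p-values of these genes ran from 0.00221 (Etv6) to 0.0447 (Runx1). Etv6 passed whichever library was left out, and Hlf, Meis1, Erg and Runx1 did not pass without Tet3_cKO replicate 1 (adjusted p from 0.127 for Hlf and Erg to 0.139 for Runx1), without Tet3_cKO replicate 2 (0.132 for Erg to 0.188 for Runx1) or without control replicate 1 (0.0555 for Meis1 to 0.102 for Runx1). Without control replicate 2, Meis1 (0.0933) and Erg (0.0635) did not pass either. When adjusted over the list alone, 13 of the 27 passed, and 13 were higher and 0 lower at an unadjusted p under 0.05. Whatever the p, 19 were higher and 8 lower, with a median of 1.63 points. Medians were larger for housekeeping (3.46), mast cell, basophil and eosinophil (3.07), myeloid (2.38) and erythroid genes (2.18). They were also larger for stromal (2.03), inflammation (1.72) and mature T and natural killer genes (1.64), and smaller for the other lists. Etv6, Runx1 and Erg held 3133, 3247 and 2710 CpGs, and the influence of gene length on the calls was not tested. Of the other lists, 3 had a called member. Prtn3, a serine protease of neutrophil granules, rose from 12% to 31.6% (1 of 20 myeloid genes, 4 adjusted over the list alone). Pax5, the B cell commitment factor, rose from 57.9% to 60.9% (1 of 20 lymphoid genes, 2 over the list alone), a call that ended in variant-poor windows alone (adjusted p = 0.0514) and with any library left out (0.0937 to 0.205), and Impact from 56.8% to 65.6% (1 of 16 imprinted genes, 1 over the list alone); without marked CpGs the rise of Impact was 4.17 points (adjusted p = 0.148). Adjusted over the list alone, 5 erythroid, 4 developmental and 2 housekeeping genes and 1 each of the stromal and of the mast cell, basophil and eosinophil genes passed too, and 0 of the other lists. The tested bodies lay on chromosome 11 from 90336535 to 90389916 (Hlf) and from 18880428 to 19018650 (Meis1), on chromosome 6 from 134036700 to 134270158 (Etv6) and on chromosome 16 from 95359169 to 95585599 (Erg) and from 92601466 to 92825073 (Runx1). Hlf and Impact lay in variant-rich windows.

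Across 17642 gene bodies, 98 rose and 1 fell with limma. The largest rises were in H2-Oa, an MHC class II accessory chain (46.5% to 69.9%, log2 odds ratio 1.40 ± 0.21 SE, adjusted p = 0.0337), Prtn3 (19.7 points, 1.74 ± 0.25, adjusted p = 0.0303), Cracr2b (17.6 points), Khdc3 (16.9 points) and the MYC family gene Mycn (9.80% to 23.0%, 1.47 ± 0.16, adjusted p = 0.0101). H2-Oa lay on chromosome 17 (34093379 to 34095234), Prtn3 on chromosome 10 (79879667 to 79882173) and Mycn on chromosome 12 (12936093 to 12940835). The zinc finger gene Zfp503 (chromosome 14, 21983959 to 21988600) fell from 13.9% to 6.07% (adjusted p = 0.0484). Of the bodies that did not pass, Gtpbp3 (−6.94 points), Tprgl (−9.68), Mindy2 (−5.66) and Fbxl12 (−9.86) had the lowest p among those lower in Tet3_cKO. The bodies of Tet3 (1.15 points), Tet1 (0.683), Tet2 (0.712), Dnmt1 (1.47), Dnmt3a (1.59), Dnmt3b (1.07), Tek (−1.42), Gata2 (−0.0908), Spi1 (1.88), Kit (1.63) and Klf1 (7.48) did not pass. The Tek body included windows with extra calls in Tet3_cKO, from 94745001 to 94747000. Across all bodies the median difference was 0.902 points, and 71.4% were higher in Tet3_cKO. At an unadjusted p under 0.05 there were 2504 higher and 123 lower, against 382 and 406 bodies in the other splits, which called 0 and 1. The other splits gave 2.17% and 2.30% of tested bodies at that threshold and may understate what unchanged bodies would give. By edgeR 62 bodies rose and 1 fell, and 62 of its 63 calls were shared with limma, while Erg, Runx1 and Pax5 were not called. Called bodies lay in windows whose marked CpGs separated the groups in 35 of 99 cases (35.4%), against 3.93% of tested bodies, and in variant-poor windows alone 42 rose and 1 fell. Leaving out control replicate 1 or 2 gave 38 and 1 or 52 and 5 bodies higher and lower, leaving out Tet3_cKO replicate 1 or 2 gave 8 and 0 or 12 and 0, and without weights 1 body was called, none of the 14 that the rule for named genes took. Of these 14 calls, 13 ended without Tet3_cKO replicate 1, 11 without Tet3_cKO replicate 2, 9 without control replicate 1, 6 without control replicate 2, and that of Impact also ended without marked CpGs.

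**Figure D4:**
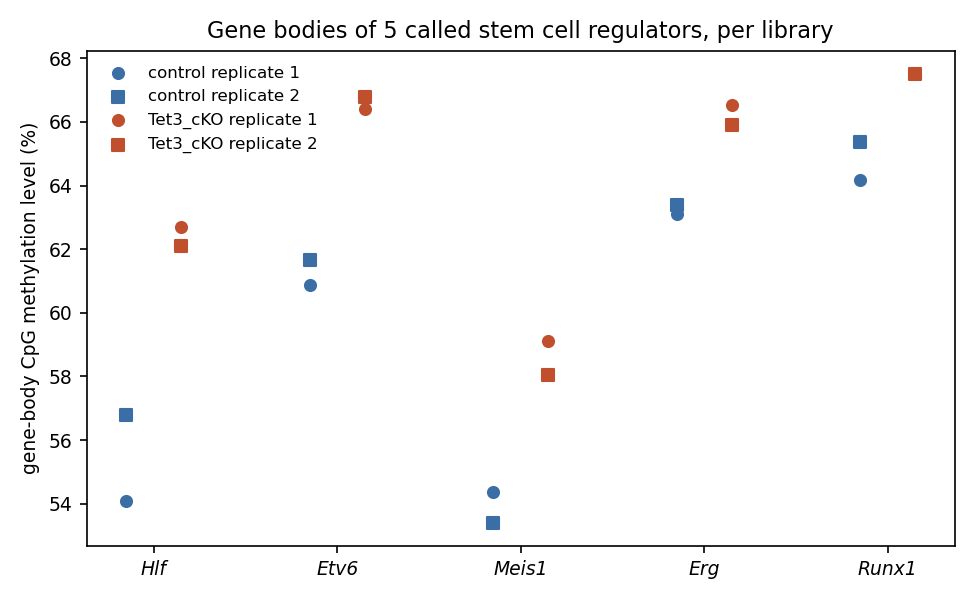
Methylation level in percent of the gene bodies of the 5 called stem cell regulators named in the text, with a point per library. Both Tet3_cKO libraries lie above both control libraries in each gene, by 2.75 points (Runx1) to 6.96 points (Hlf) on average; the axis does not start at 0.

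At gene ends no single gene passed. Of 19985 low-methylated gene ends, 0 were called by limma (lowest adjusted p = 0.579) and 0 by edgeR. At an unadjusted p under 0.05 limma gave 1150 higher and 301 lower and edgeR 1108 and 299, against 899 and 834 in all for the other splits. The median difference was 0.916 points, and both Tet3_cKO libraries lay above both controls at 25.3% of ends and below both at 11.2%. The ends of lowest p among the higher ones, none of which passed, were those of Yaf2, a YY1-binding Polycomb component (0.05% to 4.18%), Grrp1 (25.7% to 49.7%), Raly, an RNA-binding protein (1.82% to 10.9%), Bin2, a membrane-shaping protein of leukocytes (9.62% to 32.5%), and Taf11, a subunit of TFIID (3.05 points). Among the lower ones they were Apex1, the base excision repair endonuclease, whose window is shared with Osgep (5.60% to 0.612%), Akt1s1, an mTORC1 subunit (5.25% to 0.433%), Trim7 (33.7% to 4.47%) and Alyref2, an mRNA export factor (17.1% to 1.03%). Osgep itself stood at 5.45% and 0.763%. The ends of Grrp1, Raly, Bin2, Taf11 and Alyref2 lay in variant-rich windows. That of Alyref2 lay within the segment of chromosome 1 from 163 to 178 Mb, with more marked CpGs in control. A UMR that overlaps the Grrp1 end was called (17.1% to 38.7%, limma adjusted p = 0.0387). The ends with the widest differences lay at 134250102 to 134252101 on chromosome 4 (Grrp1), 100668503 to 100670502 on chromosome 15 (Bin2) and 48825138 to 48827137 on chromosome 11 (Trim7). The gene ends of Tet1, Tet2 and Tet3 differed by 0.454, 1.70 and 2.82 points, and those of Dnmt1, Dnmt3a and Dnmt3b by −3.32, 5.35 and 0.873 points. In control and Tet3_cKO the window of Dnmt1 stood at 77.1% and 73.8% and that of Dnmt3a at 68.5% and 73.9%. At these levels neither window can be taken for an unmethylated promoter. Among blood regulators the differences were −1.48 points at Gata2, 0.787 at Runx1, 3.79 at Spi1, 0.154 at Klf1, 0.919 at Kit and −0.837 at Meis1. The end of Tek (−4.41 points) was covered by 173 and 250 calls in control and 2997 and 2878 in Tet3_cKO. The X-linked Gata1 was not tested and stood at 68.0%, 67.5%, 68.6% and 61.2% in the 4 libraries.

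Of the 15 gene lists, 0 passed at gene ends with camera, and the lowest adjusted p was 0.172 (0.664 with an estimated correlation). Endothelial genes had a median difference of 6.29 points with 9 of 10 higher, among them the sialomucin Emcn (21.9 points) and the guidance receptor Robo4 (14.0). Myeloid genes had a median of 3.79 points with 18 of 23 higher, including Cebpa, the granulocyte factor (1.73 points), and the Fc receptor Fcgr3 (5.68 points). Fcgr3 was the only member of any list called when adjusted over the list alone (limma adjusted p = 0.0426), and all other lists had 0. Its window lay in a variant-rich window of chromosome 1, within the segment from 163 to 178 Mb with more marked CpGs in control. It had 1867 and 2094 calls in control and 2886 and 2526 in Tet3_cKO. Stem cell regulators had a median of 0.962 points with 18 of 28 higher (Hoxb4 9.99 points, Prdm16 −4.14), and lymphoid genes 2.82 points with 19 of 22 higher (Tcf7 7.26, Foxo1 −1.90). Mast cell, basophil and eosinophil genes had a median of 3.98 points (Ms4a2 11.5, Prg2 9.51), megakaryocyte genes 1.03 points (Gp1ba 10.1, Itga2b 7.77) and mature T and natural killer genes 3.12 points (Nkg7 9.77, Cd4 4.64). Inflammation genes had a median of 3.31 points (Tnf 10.6, Il10 13.9) and housekeeping genes 1.23 points (Sdha 3.13, Polr2a 0.820). Stromal genes had a median of −0.783 points (Col1a1 −7.50, Bglap 8.69) and developmental genes −0.0935 points (Sox1 −2.82, T −4.93). For 4 lists the signs disagreed. Erythroid genes (Sptb −2.60, Nfe2 −2.91) had a median of −0.124 and a mean of 0.908 points, germline genes (Dazl 6.10, Tdrkh 4.82) a median of −2.06 and a mean of 0.326, imprinted genes (Zrsr1 −6.34, Igf2r 3.27) a median of 0.940 and methylation machinery genes (Mbd4 4.84, Idh1 −4.23) a median of 0.873, while camera placed all 4 lower relative to the other genes.

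CpGs that carry the CpGx mark, whose meaning is not given in the sources used here, were not spread evenly. Variant-rich windows made up 26.0% of the autosomal windows, and in 106 windows the density separated the groups by at least 1.5 times at 4 per 1000 or more, 104 with more marked CpGs in both control libraries and 2 with more in both Tet3_cKO libraries. The longest segment spanned 52 to 111 Mb of chromosome 13, with 22.4 and 23.1 marked CpGs per 1000 in control and 8.38 and 8.62 in Tet3_cKO. Others lay on chromosome 18 from 5 to 21 Mb, on chromosome 1 from 145 to 160 Mb and from 163 to 178 Mb, and on chromosome 13 from 40 to 48 Mb. Without marked CpGs the autosomal difference was 0.757 points and that of LMRs 8.24 points, and in variant-poor windows they were 0.748 and 8.40 points. Mitochondrial CpGs, which stand in for unmodified DNA, were read as methylated in 2.27% and 2.51% of calls in control and 2.75% and 1.99% in Tet3_cKO, a difference of −0.0207 points.

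**Figure D5:**
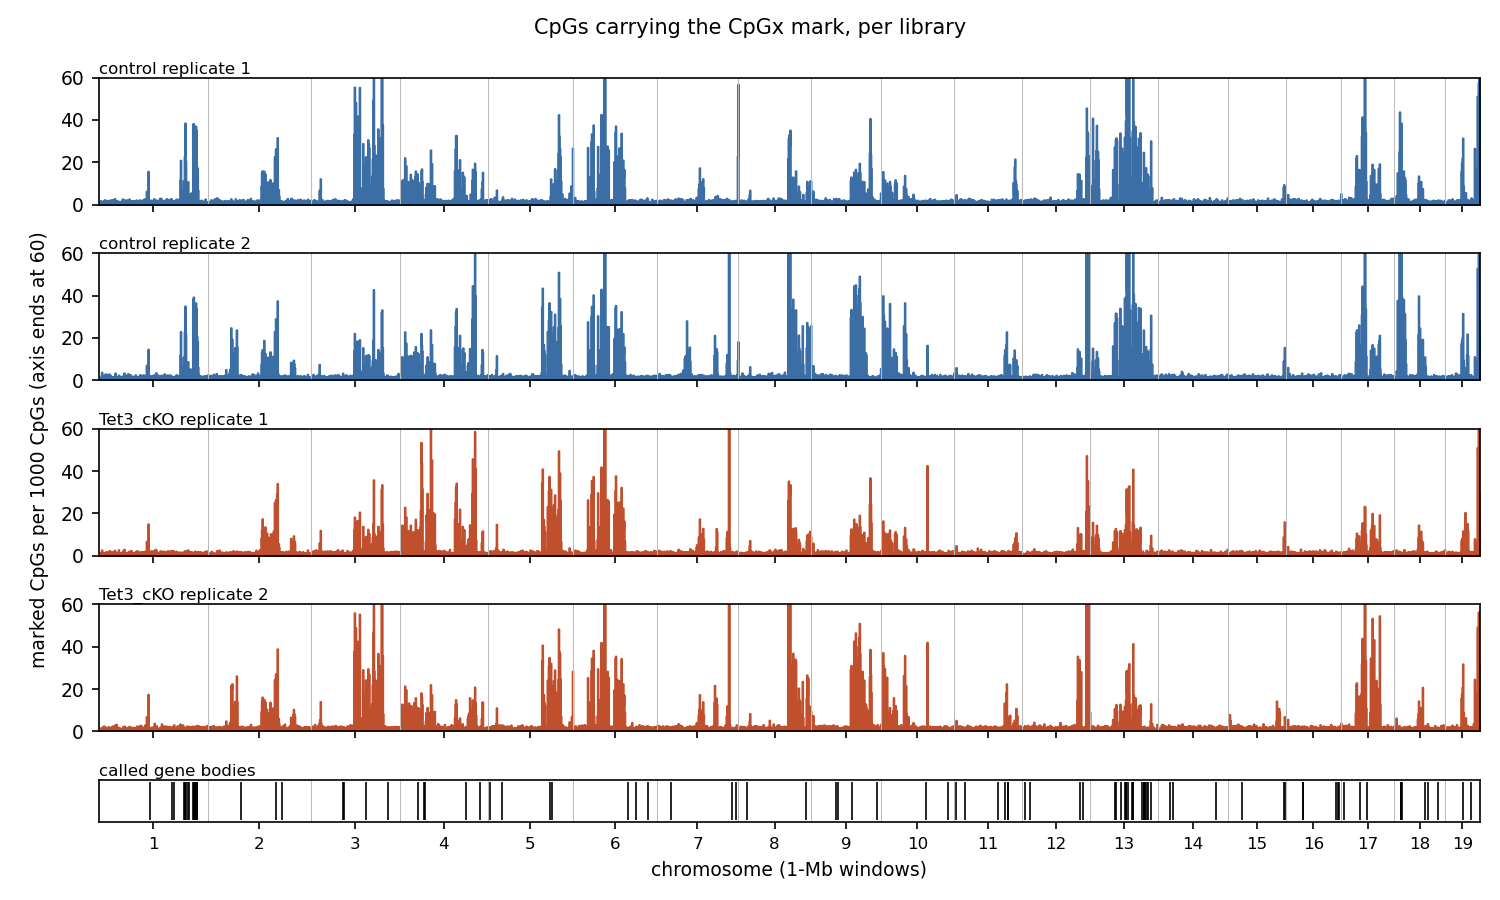
Marked CpGs per 1000 CpGs in 1-Mb windows along the 19 autosomes, with a panel per library and axes that end at 60, above the positions of the 99 called gene bodies. The control panels stand higher than the Tet3_cKO panels across 52 to 111 Mb of chromosome 13, with 22.4 and 23.1 against 8.38 and 8.62 marked CpGs per 1000.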

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

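Except for leaving out 1 library, which was planned, the tests in this part were chosen only after the results they bear on were seen. Signals outside the measured levels stood out in the marked CpGs and in the coverage. The tests of methylation compared neither between the groups. Call counts did set the weights and minimums of those tests, and marked CpGs were included in them unless stated. Both Tet3_cKO libraries had at least 1.5 times the density of marked CpGs of both controls, at 4 per 1000 or more, in 2 windows of 1 Mb. On chromosome 4 from 135 to 136 Mb there were 7.52 and 7.65 marked CpGs per 1000 in Tet3_cKO (mean 7.58) against 1.53 and 1.85 in control, and on chromosome 10 from 82 to 83 Mb 42.7 and 42.1 against 1.03 and 16.6. In the coverage, 5 variant-poor autosomal windows of 1 kb, of those with at least 3 CpGs and 100 calls in both Tet3_cKO libraries, had at least 5 times the relative calls there, all at Tek.

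LMRs were higher in Tet3_cKO by 8.11 points. Against sequence variants as the cause, if the marks stand for them, LMRs in variant-poor windows differed by 8.40 points, where the highest other split of the libraries gave 1.06. Against incomplete conversion, the LMR gain would need 10.5% of unmodified cytosines to stay unread and would raise mitochondrial CpGs by 10.2 points, and their difference was −0.0207 points. Near the genes of all 7 lineage lists the median LMR difference lay above 0 by more than 2 SE. The lowest was 4.73 ± 1.0 points (SE) near lymphoid genes, against 7.29 points over all LMRs. These values cannot decide on a gain of 1 listed blood lineage, which could lower the difference near its genes without taking it below 0. The SE also treats LMRs of the same 4 libraries as independent. A candidate explanation is the loss of TET3 activity at these regions, a hypothesis found on these data and not itself tested. Sex alone does not account for the gain, which was 7.83 points without Tet3_cKO replicate 2, the only library with different X and Y coverage. A gain of 1 lineage stays open. A shift in several cell types at once and the background of the strains also stay open and were not tested.

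Called gene bodies lay in windows whose marked CpGs separated the groups in 35.4% of cases, against 3.93% of tested bodies (odds ratio 14.0, Fisher's exact p = 1.8e-24). The Fisher p takes gene bodies as independent, though many of these calls are neighbours in a few segments, so it overstates the evidence. If the marks stand for variants, the excess could come from sequence variants that differ between the control and Tet3_cKO mice, for part of the calls. Examples are Mctp1 and Iqgap2 on chromosome 13, chosen after their values were seen. A fit of variant-poor windows alone still called 43 gene bodies, among them Etv6, Erg and Prtn3. The highest other split there called 0, a count that the genotype difference in its residual variance can lower. With 2 libraries per group there are too few splits for a share under 0.05. A body was placed by the window of its low-methylated end and can reach into a variant-rich window, so this fit cannot exclude variants. Without marked CpGs 88 bodies were called, 72 of them among the 99 of the main fit. For the calls inside the group-separating windows, variants that change methylation nearby and loss of TET3 were not separated.

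The extra calls at Tek reached 21.8 times the control level in 1 window. Extra copies of Tek sequence carried by the Cre transgene could give them, since the 127 Tek windows with a ratio under 5 had a median ratio of 0.966 and no variant-poor autosomal window away from Tek, of those with 100 calls, gained 5 times the coverage in both Tet3_cKO libraries. A larger duplication of Tek would raise those windows as well. Methylation levels at this end of Tek in Tet3_cKO (30.4%, against 34.8% in control) are then a mixture of the gene and the added copies. The tested body of Tek also holds gained windows, so the same applies to its level. No biological explanation was tested for this pattern.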

How the results depend on the processing

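The alternatives without marked CpGs, in variant-poor windows and without high-coverage CpGs in sequence classes were added after the data were seen; the others were planned. The autosomal difference kept its direction in all alternatives, from 0.475 points (minimum of 10 calls) to 0.927 (leaving out 1 library), and all 19 autosomes were higher in each of theirs. The coverage of the Tet3 and Tek windows moved by less than the replicate spread. Of 154 values for 22 sequence classes under alternatives, 148 had the same direction. Gene ends gave 0 calls with limma in every alternative and with edgeR, which was run in 1 setting, with 961 to 1616 at an unadjusted p under 0.05, and 135 list values gave 0 calls. With 6 to 7 calls per CpG and 2 libraries per group, simulated differences of 30 points were found in 37.9% of tiles and 27.3% of low-methylated regions; how much of this comes from depth was not tested. Fits that leave 1 library in a group assume that it varies like the other group. Without weights the calls of all named tiles, low-methylated regions and gene bodies ended. The Tek window gave no value without high-coverage CpGs, since it has none below the limit. Unless stated, the cause of a change was not tested.

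The replicate numbers did not pair the libraries, since the replicate differences of the groups correlated by 0.00265 over tiles and −0.0182 over gene bodies. With the replicate block 6087 tiles were higher and 1065 lower, 182 gene bodies and 565 low-methylated regions higher and 17 of the latter lower; the list and gene end calls did not change.

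With a minimum of 10 calls per CpG, classes turned to −0.131 points (11 to 20 CpGs per kb), −0.255 (21 to 40), −0.00298 (tiles of 50 to 70%), −0.232 (70 to 90%) and −0.158 (outside low-methylated regions). Tile counts (higher and lower) were 652 and 39 for tiles of 5 kb, which are fewer, 48 and 11 without weights, and 2601 and 375 at an adjusted p under 0.1. Gene body counts were 62 higher by edgeR, 1 and 0 without weights, 317 and 5 at 0.1, and 42 higher in variant-poor windows, where fewer were tested. Low-methylated region counts were 5 higher with a minimum of 50 calls, 721 and 7 by edgeR, 4 higher without weights, 1293 and 34 at 0.1, 0 higher for regions under 30%, and 160 and 4 in variant-poor windows.

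List medians at gene ends turned to 1.17 points (erythroid), 0.233 (germline) and 1.39 (stromal) in a window of 2000 bp out and 500 bp in, to 0.251 (erythroid) without marked CpGs, and to −0.285 (megakaryocyte) and 0.646 (stromal) in variant-poor windows. In a window of 200 bp to each side, the gene ends of Prdm16 (1.2), Sptb (0.189), Foxo1 (0.756), Tcf7 (−2.08), Prg2 (−0.537), Sdha (−0.152), Polr2a (0), Tek (0.503), Kit (−0.279) and Tet3 (−4.44) lost their direction. In the window of 2000 and 500 bp those of Foxo1 (2.10), Col1a1 (1.03), Zrsr1 (1.04), Tnf (−0.860), Kit (−3.37), Gata2 (0.193) and Meis1 (0.882) did. The body of Tek turned to 0.817 points without high-coverage CpGs. None of these passed the test in any setting.

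With each library left out in turn, the class of tiles of 90 to 100% ranged from −0.128 to 0.359 points, that of 70 to 90% from 0.00382 to 0.234 and canyons from 3.69 to 7.95. Tiles ranged from 173 to 625 higher and from 93 to 128 lower, gene bodies from 8 to 52 and from 0 to 5, and low-methylated regions from 0 to 190 and from 0 to 6. List medians ranged from −0.0990 to 0.00901 (developmental), −2.25 to 0.740 (erythroid), −2.02 to 2.27 (germline), −0.202 to 2.08 (imprinted), −0.541 to 5.57 (mature T and natural killer), −1.41 to 1.63 (methylation machinery) and −2.89 to 0.251 (stromal). Gene ends ranged from −0.198 to 7.77 (Spi1), −1.76 to 3.5 (Dnmt3b), −13.6 to 4.76 (Tek), −4.31 to 1.34 (Gata2), −2.47 to 2.77 (Klf1), −2.19 to 3.09 (Tet1), −3.19 to 1.52 (Meis1), −0.842 to 11.6 (Dnmt3a) and −1.22 to 2.79 (Runx1). Gene bodies ranged from −0.246 to 2.55 (Tet3), −0.709 to 0.527 (Gata2) and −0.407 to 3.34 (Dnmt1).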

Other observations

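The tests in this part were chosen only after the data were seen. LMRs near the genes of the lists differed in how far they lay above the controls. Within 20 kb of endothelial genes the median LMR difference was 14.0 ± 1.70 points (SE), with 50 of 57 LMRs higher (camera adjusted p = 0.0336; adjusted p = 0.507 with an estimated correlation). Near stem cell regulators it was 9.82 ± 0.857 points with 205 of 242 higher (adjusted p = 0.114), and per gene the median was 20.3 points at Hlf, 14.9 at Ly6a, 14.8 at Erg and Etv6, 14.7 at Lmo2, 11.9 at Meis1 and 10.2 at Runx1. Near myeloid genes and mast cell, basophil and eosinophil genes it was 8.74 points, near erythroid genes 8.50 and near megakaryocyte genes 7.33. LMRs near imprinted genes had a median of 2.49 ± 1.22 points, lower relative to the other LMRs (adjusted p = 0.000473; adjusted p = 0.406 with an estimated correlation). Near developmental genes the median was 3.51 points, near inflammation genes 8.40, germline genes 8.31, methylation machinery genes 7.19, stromal genes 6.94, mature T and natural killer genes 5.84 and housekeeping genes 4.85.

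In gene bodies, the stem cell and erythroid lists rose relative to the other genes with camera at the preset correlation. For stem cell regulators the adjusted p was 0.0083, and adjusted p = 0.635 with an estimated correlation; in variant-poor windows alone the preset value was 0.0427. For erythroid genes it was 0.0187, again with adjusted p = 0.635 with an estimated correlation and 0.0427 in variant-poor windows. Of 14 erythroid gene bodies, 13 were higher, 0 were called by limma over all genes (6 higher and 0 lower at an unadjusted p under 0.05) and 5 were called when adjusted over the list alone. The other 13 lists did not pass.

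LMR gain may be larger near stem cell regulators than near lymphoid genes. The median over genes was 8.36 points for 20 stem cell regulators and 6.44 points for 22 lymphoid genes, among which Cd79b (16.4) and Notch1 (11.9) were high and Il7r (−5.55) was low. The difference of 1.92 points had a permutation p of 0.213 (100000 resamples, 2-sided), so these data leave the hypothesis open.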
